A study of Mus musculus with 8 samples.

How the data were processed

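RNA was measured in a transgenic mouse embryonic stem (ES) cell line called Dazl-GFP, grown on irradiated feeder fibroblasts in serum with leukemia inhibitory factor and the inhibitor pair known as 2i, which blocks the kinases MEK and GSK3β. Per the labels' protocols, cell lysates went through native RNA immunoprecipitation (IP), that is, without crosslinking, with an antibody against GFP or against the poly(A) binding protein PABP1. RNA was then extracted with TRIZOL. The 8 arrays form 3 groups taken from the antibody in the labels: 3 inputs with no antibody, 3 GFP IPs and 2 PABP1 IPs. No IP with a control antibody was analysed here, so RNA that sticks to beads or antibody is not separated from RNA that is bound. The sources used here do not give whether GFP is joined to the DAZL protein in this line or reports the activity of the gene.

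Each array was a 1-colour Agilent array of design 014868, labelled with Cy3. Per the file headers, the authors' intensity values were made with Feature Extraction 9.1.3.1 and protocol GE1-v5_95_Feb07, with an extended dynamic range scan. Per the file headers, that software also subtracted background, removed spatial trends within each array, and replaced the intensity of dim spots by a surrogate. Flags for saturation, for outlier spots and for signal well above background, which are other values than brightness, were deposited in the same files. The authors also deposited a table of group mean intensities, scaled to medians of 0.995 for input and 1.02 for each IP; how its arrays were scaled is not given in the sources used here. Its ratios ranked genes much as those computed here, with correlations across 7422 genes of 0.996 for the GFP IP over input, 1.00 for the PABP1 IP over input and 0.998 for the IPs against each other, but they were shifted. Its median log2 ratios were 0.00, 0.34 and −0.25, against −0.54, 0.25 and −0.73 here. That table's error columns are not tied to groups by name and were not used here.

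The processed intensity was taken to log2, and the 75th percentile of each array over its 43379 probe spots was subtracted. Spots of a probe were averaged, which left 41174 probes, and 30 probes with an outlier spot were left out. Accessions on the array were named through a RefSeq gene table of assembly GRCm38.p6, without versions. Among the tested genes, 10725 were matched by accession, 1450 by symbol and 780 by an older synonym, 12955 in all, while 1715 kept the array's own name. For a gene with several probes, the probe with the highest mean over the 8 arrays stood for the gene. Of 27666 genes, 14670 were well above background on every array of at least 1 group and were tested, and 11372 were well above background on all arrays. Other probes of called genes had the same sign in 76.7% of cases for the GFP IP over input, 78.6% for the PABP1 IP over input and 79.4% between the IPs. No genome or probe sequence was used here, so where probes lie in their transcripts, and the length or motifs of 3′ untranslated regions, were not analysed here.

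Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 8 arrays, 5 residual and 2.11 prior degrees of freedom), with the data.table package (version 1.17.8) for reading. P-values are two-sided and were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The labels do not state that arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. A gene well above background on no array of 1 of the groups has only a bound on its fold, and no such gene is named with a fold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

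Groups of genes were 22 fixed lists: TET enzymes and active demethylation, DNA methylation, DAZL targets described in germ cells, naive pluripotency, core pluripotency, primed pluripotency, germ cell and meiosis, feeder fibroblast markers, primitive endoderm markers, two-cell-like markers, cytosolic ribosomal proteins, translation factors, replication-dependent histones, mitochondrially encoded mRNAs, the nuclear-encoded respiratory chain, nuclear and long non-coding RNAs, Polycomb, mitosis, apoptosis, the proteasome, proteins made at the endoplasmic reticulum (ER), and RNA granule and 3′ untranslated region regulators. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where a later choice is stated. Lists were tested with limma's camera at its preset correlation of 0.01 between genes, with adjustment over the 21 lists that had at least 3 tested members; the correlation estimated from the data and the rotation test fry were alternatives. Each list's median was also placed among 10000 random lists matched on input level and drawn from all tested genes, members of the list included. The mitochondrially encoded list held 26 names and 0 tested genes. An older synonym had first matched one of its names to the nuclear gene Ptgs1, which was seen in the results, and synonyms were then dropped for that list.

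The named genes were Dazl, Pabpc1 and the TET genes; per direction the 8 largest changes among genes passing the test, with arrays that did not overlap between groups and signal well above background on every array of both, leaving out names that are clones or gene models; 2 members of each list that passed; and the tested members of the DAZL target list. The probe that stood for Tet3 was not above background on every array of any group, so Tet3 was not tested. Another Tet3 probe, well above background on 3 of the 8 arrays, read 1.52 in GFP IP over input, −0.88 in PABP1 IP over input and 2.40 between the IPs.

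Between 41.5% and 52.6% of probe spots were well above background per array, and 0 were saturated. The number of arrays limits the precision. GFP IP 3 had a spread (SD) of negative-control spots of 5.02, against 1.21 to 1.99 on the others, and 44.4% of its spots were well above background. Spike-in RNA added at labelling had a median net intensity of 688 to 753 in the PABP1 IPs and 2560 to 4350 elsewhere. The 8 arrays lay on 2 slides of 4 arrays. Slide 1 held input 3, the second PABP1 IP and GFP IPs 1 and 3, and slide 2 held the others.

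The test of single genes was tried on 14670 simulated genes with the real spread, where each IP had known changes of log2 1, 2 and 3 in 67, 67 and 66 genes. For the GFP IP over input it recovered 50.7%, 85.1% and 90.9% of genes changed by log2 1, 2 and 3, and 12 of 163 calls were false (7.36%). For the PABP1 IP over input the shares were 38.8%, 83.6% and 89.4%, with 6 of 147 calls false (4.08%). For the comparison of the IPs they were 47.0%, 87.2% and 93.1%, with 13 of 314 calls false (4.14%). The simulation changed far fewer genes than passed in the data, where GFP IP over input had 9489 calls. The adjusted threshold depends on that share. Noise was also drawn independently for each array, without a slide effect. These shares therefore need not hold for the data.

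Alternatives were normexp background correction (offset 50) on the raw mean and background intensities, quantile normalization, scaling to the median, the 75th percentile over probes well above background on all arrays, no filter or a stricter filter on dim probes, the mean of a gene's probes, the replicate number or the slide as a block, array weights, another model of the spread, only the groups compared, a 2-fold minimum, the authors' deposited table, and leaving out each array. The estimation of array weights gave convergence warnings, so results with array weights are less certain. Fits to slide 1 alone and slide 2 alone, and centring each array on its median ratio to the inputs, were chosen after seeing the data. Results for some genes that met the rule for naming are not reported here.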

Results

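RNA recovered by immunoprecipitation was profiled in mouse ES cells of the Dazl-GFP line in 2i. DAZL is a germ-cell RNA-binding protein that binds mRNAs in their 3′ untranslated regions, and the study asked which RNA species it binds. The 8 one-colour arrays comprised 3 inputs (total RNA), 3 GFP IPs and 2 PABP1 IPs. PABP1 coats the poly(A) tails of mRNAs in general, so its IP was used here as a reference, although its own recovery was selective. On each array 41.5% to 52.6% of 43379 spots were well above background, and 14670 genes were tested. Values below are differences in mean log2 signal over the array's 75th percentile, with limma's standard error and adjusted p; they compare an mRNA's share of one RNA sample with its share of another.

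Arrays of a group resembled each other more than arrays of different groups. Across genes, which are not independent replicates, the correlation of log2 signal was 0.975 to 0.993 within groups. It was 0.903 to 0.933 between input and GFP IP, 0.890 to 0.914 between input and PABP1 IP, and 0.857 to 0.901 between the IPs. The first principal component, with 57.6% of the variance, parted the PABP1 IPs from the GFP IPs, and the second, with 33.5%, parted the inputs from both IPs. The third component, with 6.66%, followed the slide.

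**Figure D1:**
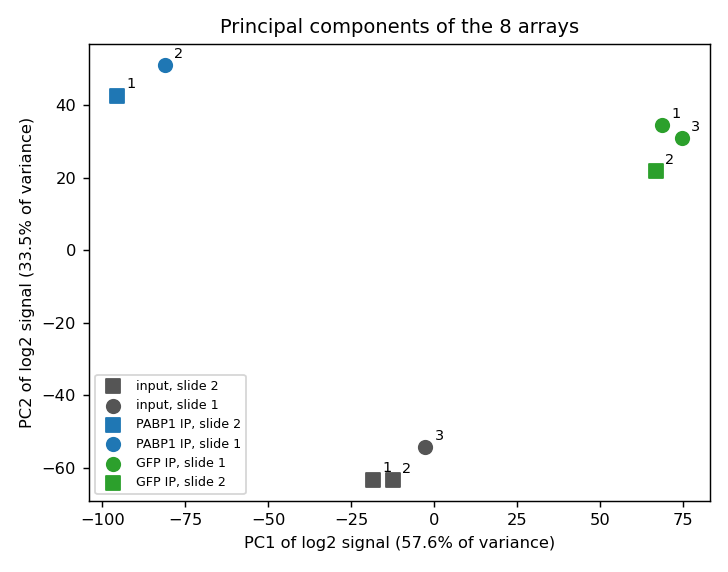
Scores of the 8 arrays on the first principal component (horizontal, 57.6% of the variance) and the second (vertical, 33.5%), computed from log2 signal; each point is an array, numbered within its group, coloured by group and shaped by slide. Inputs, PABP1 IPs and GFP IPs lie apart, with both slides present in each group.

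The first comparison, GFP IP over input, addressed which mRNAs the GFP antibody recovered. Dazl mRNA itself was 14.1-fold higher in the GFP IP (log2 3.81 ± 0.21, adjusted p = 2.16e-05), rank 16 of 14670. Its second probe was well above background on the 3 GFP IPs and on 0 of the other arrays, which bounds its difference from input at 5.59-fold or more. Tet1 and Tet2, which encode the enzymes that oxidise 5-methylcytosine and give the study its title, did not pass: Tet1 stood at 0.00 ± 0.25 (adjusted p = 0.993) and Tet2 at 0.28 ± 0.12 (adjusted p = 0.0719). Pabpc1, which encodes PABP1, did not pass either, at −0.86 ± 0.61 (adjusted p = 0.246), although it passed with array weights (−1.66, adjusted p = 0.00736) and on slide 1 alone (−0.71, adjusted p = 0.0477). A second Tet2 probe, well above background on 5 of the 8 arrays, read −0.35.

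The median of all tested genes was itself shifted, to −0.52 in this comparison, 0.24 in PABP1 IP over input and −0.68 in GFP IP over PABP1 IP. Relative to the median gene, Dazl was at 4.33, Tet1 at 0.51, Tet2 at 0.80 and Pabpc1 at −0.34. At 0.00 over input, Tet1 had no clear sign, and its value moved with the scaling. It was 0.53 with scaling to the median, where it passed limma (adjusted p = 0.0315). It was 0.08 with quantile normalization, 0.16 with the 75th percentile over probes detected on all arrays, 0.46 after centring and −0.01 with normexp. Tet2 passed with scaling to the median (0.82, adjusted p = 0.00629), after centring (0.75, adjusted p = 0.00141), with the percentile over detected probes (0.45, adjusted p = 0.0115) and with slide as a block (0.31, adjusted p = 0.0357). In the authors' deposited table Tet1 was at log2 0.51 and the median ratio at 0. Within slides 1 and 2 Dazl was at 3.81 and 4.14 (3.93 with slide as a block), Tet1 at 0.19 and 0.17 (0.17), and Tet2 at 0.30 and 0.36 (0.31).

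**Figure D2:**
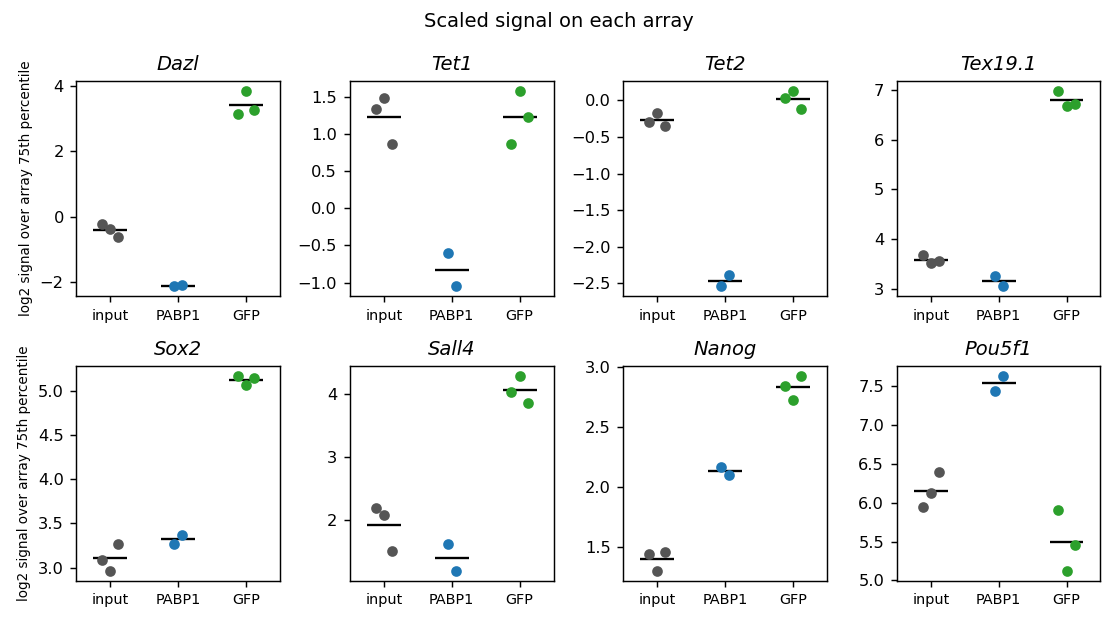
Log2 signal over the array's 75th percentile (vertical) for 8 genes in inputs, PABP1 IPs and GFP IPs (horizontal); each point is an array and each line a group mean. Dazl was at 3.13 to 3.84 in the GFP IPs and −0.61 to −0.23 in the inputs, while Tet1 overlapped between the same groups, with a mean difference of 0.00 that became 0.53 with scaling to the median.

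Other mRNAs far above input encoded proteins of unrelated functions. Dck, a deoxynucleoside salvage kinase, was 31.7-fold higher (4.98 ± 0.18, adjusted p = 1.30e-05), and Cd38, an NAD-hydrolysing surface enzyme, followed at 4.26 ± 0.12 (adjusted p = 1.30e-05). Tex30 (4.37), the co-chaperone gene Dnajc12 (4.01), the ubiquitin ligase gene Siah2 (3.95), Cggbp1 (3.93), which encodes a CGG-repeat binding protein, the transcriptional repressor gene Dr1 (3.91) and Coq10b (3.90) were next. At the other end, Malat1, a non-coding RNA retained in the nucleus, was 31.5-fold lower (−4.98 ± 0.34, adjusted p = 4.02e-05). Marf1 (−4.04), Gdap10 (−3.76), the nuclear pore gene Tpr (−3.66), the giantin gene Golgb1 (−3.62), Nemf (−3.58), which encodes a ribosome quality-control factor, the kinase gene Mink1 (−3.44) and the snoRNA host gene Snhg11 (−3.41) were also lower. These extremes were partly shared with the PABP1 IP. Each higher gene named here also stood above input with PABP1, from 0.56 for Dr1 to 2.94 for Dnajc12, though less far than with GFP. Tpr (−5.91), Golgb1 (−5.60), Nemf (−4.90) and Mink1 (−4.81) were further below input with PABP1 than with GFP, and so were the other lower genes as measured. Probes of some of these genes differed in size. Among those higher, other probes gave 0.81 for Cd38, 2.19 for Dr1, and 2.40 and 3.26 for Dck, each well above background on only some arrays, and 3.52 for Tex30. Among those lower, other probes gave −1.09 for Tpr, −1.96 for Nemf, −0.53 for Mink1 and −1.29 for Snhg11.

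mRNAs described as DAZL targets in germ cells were recovered with the GFP IP: of 11 tested, 9 were higher, 2 were lower, and the same counts held adjusted over the list alone. Tex19.1, a germline gene that restrains transposons, was 9.22-fold higher (3.21 ± 0.13, adjusted p = 1.33e-05). The pluripotency factors Sox2 (2.03 ± 0.12), Sall4 (2.13 ± 0.23) and Nanog (1.43 ± 0.11), the Polycomb subunit Suz12 (1.94 ± 0.22), the caspases Casp9 (1.66 ± 0.21) and Casp2 (1.49 ± 0.12), and Sdad1 (1.92 ± 0.27) were among those higher. The spindle gene Tpx2 (−1.02 ± 0.16, adjusted p = 0.00123) and the pluripotency factor Pou5f1 (−0.66 ± 0.22, adjusted p = 0.0341) were lower. The list's median was 1.92, or 2.43 above the median gene, and limma's camera gave an adjusted p of 8.85e-05, with adjusted p = 0.0818 with an estimated correlation. Within slides 1 and 2 the median was 1.82 and 1.77, and 1.80 with slide as a block. With normexp, Nanog (1.12), Casp2 (1.31), Casp9 (1.31), Tpx2 (−1.02) and Pou5f1 (−0.71) no longer passed; Pou5f1 and Tpx2 also did not pass with scaling to the median, at −0.12 and −0.49, and Pou5f1 failed with quantile normalization (−0.37), with the percentile over detected probes (adjusted p = 0.0950), after centring (0.530), without a filter on dim probes (0.0820), with the replicate block (0.0670) and on slide 1 alone (0.0837). Its call also ended without input 2 (0.0758), input 3 (0.0904), GFP IP 2 (0.0880) or GFP IP 3 (0.0893). Second probes stood at −1.56 for Sdad1, whose probe mean of 0.18 did not pass (adjusted p = 0.475), and at 0.08 for Sall4.

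Of 39 tested genes for RNA granules and 3′ untranslated region regulation, a list that includes Dazl, 20 were higher and 9 lower (also adjusted over the list alone); Zfp36l1, which binds AU-rich elements (2.52 ± 0.11), and the RNA-binding gene Elavl2 (2.20 ± 0.11) were higher as well, and camera gave adjusted p = 8.85e-05, but adjusted p = 0.0720 with an estimated correlation. Of 20 Polycomb genes, which encode histone-modifying repressors, 11 were higher and 1 lower (11 and 1 adjusted over the list alone), such as the E3 ligase gene Rnf2 (2.97 ± 0.11) and the histone chaperone gene Rbbp4 (1.89 ± 0.11). For this list camera gave adjusted p = 0.000262 and adjusted p = 0.0720 with an estimated correlation. A second Rnf2 probe read 0.87, 1 of the other Rbbp4 probes −0.89, and a second Zfp36l1 probe 1.57. Of 20 apoptosis genes 11 were higher and 6 lower (11 and 6 adjusted over the list alone), with the BH3-only gene Pmaip1 at 2.94 ± 0.13. On this set camera gave adjusted p = 0.00574 and adjusted p = 0.220 with an estimated correlation. The caspase inhibitor gene Xiap passed too, but it was well above background on 1 of 3 inputs and did not pass with normexp (0.53, adjusted p = 0.234). Of 34 genes for secreted and membrane proteins made at the ER, 16 were higher and 12 lower (17 and 12 adjusted over the list alone), among them the receptor gene Fgfr1 (1.93 ± 0.11) and the glypican gene Gpc4 (1.92 ± 0.11). Other Fgfr1 probes read 2.04, 0.88 and 0.65. Tested with camera, the list gave adjusted p = 0.0132, which became 0.0883 with the mean of a gene's probes (median −0.23), and adjusted p = 0.201 with an estimated correlation. Medians relative to the median gene were 1.16, 1.28, 1.39 and 1.02 for these 4 lists. Within slide 1 they were 0.90, 1.23, 1.41 and 0.81, within slide 2 they were 0.83, 1.20, 1.25 and 1.01, and with slide as a block 0.82, 1.24, 1.38 and 0.90.

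Respiratory chain, histone, proteasome and ribosomal protein mRNAs were lower in the GFP IP, and of these lists only the histones lay outside the range of random lists matched on input level. Of 73 genes for the nuclear-encoded respiratory chain, which makes most cellular ATP, 62 were lower and 2 higher (62 and 2 adjusted over the list alone), such as the complex I gene Ndufa5 (−2.02 ± 0.11) and the ATP synthase gene Atp5e (−1.72 ± 0.12). As a set it had a camera adjusted p = 1.13e-05 and adjusted p = 0.407 with an estimated correlation. Of 29 replication-dependent histone genes, whose mRNAs end without a poly(A) tail, 23 were lower and 1 higher (24 and 1 adjusted over the list alone), with the linker histones H1f1 at −1.88 ± 0.14 and H1f5 at −1.69 ± 0.11. The set test camera gave adjusted p = 0.00322 and adjusted p = 0.388 with an estimated correlation. Of 31 proteasome genes 21 were lower and 0 higher (21 and 0 adjusted over the list alone), including Psmb5 (−1.74 ± 0.15) and Psmd1 (−1.66 ± 0.14). Camera gave for this list adjusted p = 0.00810 and adjusted p = 0.423 with an estimated correlation, and the call ended with quantile normalization (adjusted p = 0.0523) and with the mean of a gene's probes (adjusted p = 0.0730). Of 79 cytosolic ribosomal protein genes 57 were lower and 0 higher (58 and 0 adjusted over the list alone), including Rpl35a (−1.44 ± 0.18) and Rpl27a (−1.01 ± 0.12). By camera the list had adjusted p = 0.000984, 0.450 with quantile normalization (median −0.23, or 0.04 relative to the median gene), and adjusted p = 0.692 with an estimated correlation.

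Relative to the median gene these 4 lists had medians of −0.62 (respiratory chain), −1.09 (histones), −0.28 (proteasome) and −0.58 (ribosomal proteins). Within slide 1 they were at −0.68, −1.02, −0.21 and −0.42, within slide 2 at −0.73, −1.19, −0.47 and −0.59, and with slide as a block at −0.69, −1.05, −0.31 and −0.45. Matched random lists had medians of −1.15 to −0.76 for the respiratory chain (list −1.13), −1.22 to −0.89 for ribosomal proteins (list −1.10) and −1.16 to −0.45 for the proteasome (list −0.79). These lists lay inside their ranges, at percentiles 4.45, 28.9 and 61.2, the respiratory chain near the lower edge. For the histones the range was −1.14 to −0.40 (list −1.61). The random lists could hold members of the list tested, and input level is also the denominator of the ratio. They are therefore no clean measure of other mRNAs of equal abundance. Across all genes the ratio had a Pearson r of 0.016 with mean level (Spearman 0.028). The ribosomal protein count was the least stable: 14 genes were lower and 1 higher with scaling to the median, 11 and 4 with quantile normalization, 19 and 1 after centring, and 0 and 0 with normexp, with Rpl27a and Rpl35a at −1.12 (adjusted p = 0.136) and −1.49 (adjusted p = 0.0687) there. A second Rpl27a probe read 0.09. Markers of the feeder fibroblasts moved the same way as these lists: 18 of 30 were lower and 3 higher in the GFP IP, with a median of −0.86, or −0.34 relative to the median gene, at camera adjusted p = 0.212. Relative to the median gene it was −0.57 within slide 1, −0.11 within slide 2 and −0.37 with slide as a block.

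The remaining lists did not pass camera, although DNA methylation did with slide as a block (adjusted p = 0.0443), with the replicate block (0.0444) and within each slide (0.0488 and 0.0332). With scaling to the median the naive (0.0202) and non-coding RNA (0.0139) lists passed too, and with normexp the germ cell list (0.0215), which includes Dazl and Tex19.1. Counts higher and lower were 3 and 8 of 16 for TET enzymes and active demethylation (adjusted p = 0.961), 7 and 4 of 16 for DNA methylation (0.0552), 6 and 3 of 19 for naive pluripotency (0.0886) and 8 and 5 of 17 for core pluripotency (0.0566). They were 5 and 2 of 11 for primed pluripotency (0.0988), 9 and 5 of 18 for germ cell and meiosis (0.0552), 0 and 2 of 10 for primitive endoderm (0.623) and 2 and 0 of 4 for two-cell-like markers (0.0905). They were 11 and 12 of 30 for translation factors (0.250), 1 and 8 of 12 for nuclear and long non-coding RNAs (0.0566) and 7 and 14 of 37 for mitosis (0.961). Adjusted over the list alone the counts differed only for core pluripotency (8 and 6) and primitive endoderm (0 and 1). Medians of the naive (−0.07) and primed (−0.19) lists were negative while their means (0.20 and 0.46) and camera's direction were positive, and the translation and mitosis lists had negative medians and means under an upward camera direction. The medians of the TET, naive, primed, primitive endoderm, translation and mitosis lists turned positive with scaling to the median, and that of the germ cell list negative with normexp.

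In the GFP IP over input, 3109 genes were higher and 6380 lower. With slide as a block the counts were 3572 and 7502, within slide 1 alone 2770 and 5510, and within slide 2 alone 2715 and 5893. Of the called genes 32.8% were higher, a share that became 58.8% with scaling to the median and 54.9% after centring, so the balance of directions rested on the scaling. With normexp 581 were higher and 962 lower.

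The second comparison, PABP1 IP over input, measured recovery with the poly(A) binding protein. Tm2d1 was 18.3-fold higher (4.19 ± 0.12, adjusted p = 1.39e-05), Tmem126a, a mitochondrial membrane gene, 15.2-fold (3.93 ± 0.13), and the ion channel gene Tmem38b 12.3-fold (3.62 ± 0.13). Pde6d (3.54), the replication protein gene Rpa3 (3.53), the cytochrome b5 gene Cyb5a (3.40), Spg21 (3.32) and the G-protein subunit gene Gng10 (3.30) followed. The lowest included Tpr (−5.91 ± 0.32, adjusted p = 1.94e-05), Grn, which encodes the growth factor precursor progranulin (−5.89 ± 0.38, adjusted p = 3.05e-05), Golgb1 (−5.60), the nucleolar gene Nol8 (−5.38), Syt10 (−5.23), the condensin gene Smc2 (−5.18), the centriolar satellite gene Pcm1 (−5.15) and Dzip3 (−4.92). For several of these the probe mattered: other probes read −2.48 for Tpr, −0.61 for Grn, −2.28 for Golgb1, −0.62 for Smc2, −1.99 for Pcm1 and −0.87 for Dzip3.

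Dazl and both tested TET mRNAs were poorly recovered with PABP1. Tet1 was lower by log2 −2.06 ± 0.28 (limma adjusted p = 0.000603), Tet2 by −2.19 ± 0.13 (adjusted p = 2.65e-05) and Dazl by −1.70 ± 0.23 (adjusted p = 0.000625), and relative to the median gene they stood at −2.30, −2.43 and −1.94. Within slides 1 and 2 Tet1 was at −1.92 and −2.01 (−1.97 with slide as a block), and Tet2 at −2.04 and −2.30 (−2.18). The Dazl call ended with normexp (−0.83, adjusted p = 0.312). In that setting Tet1 was at −1.30 (adjusted p = 0.0311) and Tet2 at −0.95 (adjusted p = 0.0342). Within the slides Dazl was at −1.48 and −1.82 (−1.64 with slide as a block). Pabpc1 stood at 0.22 ± 0.68 (adjusted p = 0.799), and its sign turned with quantile normalization (−0.58).

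Respiratory chain mRNAs went up in the PABP1 IP, the opposite of the GFP IP: 57 of 73 were higher and 2 lower (59 and 2 adjusted over the list alone). The cytochrome oxidase gene Cox6b1 was 5.91-fold higher (2.56 ± 0.13) and the ATP synthase gene Atp5l 6.06-fold higher (2.60 ± 0.19). The list's median was 1.21, or 0.97 above the median gene (0.92 within slide 1, 1.04 within slide 2 and 0.96 with slide as a block); limma's camera gave adjusted p = 2.60e-07 and adjusted p = 0.641 with an estimated correlation. Feeder markers were higher as well, 13 of 30 against 2 lower (11 and 2 adjusted over the list alone), with a median of 0.59 at adjusted p = 0.232; it was 0.70 and 0.52 within the slides and 0.61 with slide as a block.

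Of 39 RNA granule genes 26 were lower and 7 higher (26 and 7 adjusted over the list alone), with the Argonaute gene Ago2 at −2.73 ± 0.14 and the helicase gene Ddx6, a decapping activator, at −2.86 ± 0.15. In camera the group had adjusted p = 0.000584 and adjusted p = 0.151 with an estimated correlation. Of 16 DNA methylation genes 11 were lower and 2 higher (11 and 2 adjusted over the list alone), including Ehmt1, a histone methyltransferase gene (−1.72 ± 0.16), and Uhrf1, which recruits the maintenance methyltransferase (−1.30 ± 0.13). With camera the list had adjusted p = 0.0123, 0.0881 with normexp, and adjusted p = 0.357 with an estimated correlation. Other Ago2 probes read −1.87, −1.67 and −0.57. With normexp Ehmt1 (−1.26) and Uhrf1 (−0.99) did not pass. Relative to the median gene the medians were −1.36 and −1.29. They were −1.27 and −1.19 within slide 1, −1.54 and −1.26 within slide 2, and −1.46 and −1.28 with slide as a block.

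The DAZL target list did not move as a set with PABP1: 3 of 11 were higher and 4 lower (3 and 4 adjusted over the list alone; median −0.19, camera adjusted p = 0.642), and its median was 0.10 with normexp. Pou5f1 (1.39 ± 0.25) and Nanog (0.74 ± 0.12) were among those higher, and Sdad1 (−1.85 ± 0.30), Suz12 (−1.15 ± 0.24), Casp2 (−0.71 ± 0.14) and Tex19.1 (−0.43 ± 0.15) lower. None of these genes passed limma with normexp, Pou5f1 did not pass with quantile normalization (0.56, adjusted p = 0.120), and Tex19.1 did not pass with scaling to the median (adjusted p = 0.215). The Tex19.1 call also ended without any single input (adjusted p = 0.0614 to 0.0943), without either PABP1 IP (0.0626 and 0.199), with only the groups compared (0.0612) and on each slide alone (0.158 and 0.177). On slide 1 alone Casp2 (adjusted p = 0.0641) and Nanog (0.0672) did not pass. Sall4 (−0.52, adjusted p = 0.112), Sox2 (0.22, adjusted p = 0.207), Casp9 (0.09, adjusted p = 0.757) and Tpx2 (−0.19, adjusted p = 0.408) did not pass. Sall4 passed with slide as a block (−0.45, adjusted p = 0.0111), with the replicate block (−0.68, adjusted p = 0.0385), with array weights (−0.65, adjusted p = 0.0317) and after centring (−0.68, adjusted p = 0.0227). The sign of Sox2 and Casp9 turned with quantile normalization (−0.01 and −0.02) and that of Tpx2 with normexp (0.10).

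Other lists did not pass camera in this comparison. With slide as a block, however, ribosomal proteins passed as higher (adjusted p = 0.0219), and mitosis (0.0219), histones (0.0352) and ER-made proteins (0.0376) as lower. Non-coding RNAs passed as lower with normexp (0.0346), quantile normalization (0.0425), scaling to the median (0.0405) and the mean of a gene's probes (0.00364). Ribosomal proteins (0.000313) and the proteasome (0.0171) passed as higher with normexp. Counts higher and lower were 7 and 4 for TET enzymes and active demethylation (adjusted p = 0.884), 8 and 6 for naive (0.884), 4 and 3 for core (0.938) and 3 and 1 for primed pluripotency (0.938), 3 and 6 for germ cell (0.305), 3 and 2 for primitive endoderm (0.938) and 1 and 0 for two-cell-like markers (0.714). They were 29 and 0 for ribosomal proteins (0.0527), 10 and 7 for translation factors (0.884), 7 and 11 for histones (0.148), 3 and 6 for non-coding RNAs (0.0652), 3 and 4 for Polycomb (0.642), 8 and 16 for mitosis (0.0527), 10 and 3 for apoptosis (0.232), 15 and 5 for the proteasome (0.201) and 4 and 14 for ER-made proteins (0.0584). Adjusted over the list alone, counts were 8 and 5 for TET, 3 and 5 for germ cell, 3 and 3 for primitive endoderm, 26 and 0 for ribosomal proteins, 7 and 12 for histones and 17 and 5 for the proteasome. The naive (median 0.26, mean −0.14, camera downward), core (0.29, −0.09, upward) and Polycomb (0.02, −0.04, downward) lists had medians and means of opposite sign, and the medians of the naive, translation, Polycomb and proteasome lists turned negative with quantile normalization, at −0.45, −0.32, −0.19 and −0.10. The primed (−0.22), primitive endoderm (−0.22) and two-cell (−0.15) medians turned negative with normexp.

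In the PABP1 IP over input, 5035 genes were higher and 3711 lower (57.6% higher). With slide as a block the counts were 6354 and 4491, within slide 1 alone 4588 and 2988, and within slide 2 alone 5173 and 3550. The share higher was 47.6% with the 75th percentile over probes detected on all arrays and 72.0% with normexp, which called 1643 higher and 639 lower.

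The third comparison, GFP IP over PABP1 IP, set recovery with GFP against recovery with PABP1. The PABP1 IP was itself selective, with 3711 genes lower than input, 284 of them at least 8-fold. A gene can therefore be higher here through loss from the PABP1 IP alone. Dazl had the largest difference of all tested genes, 45.7-fold (5.52 ± 0.23, adjusted p = 9.11e-06), and Tet1 (2.05 ± 0.28, adjusted p = 0.00045) and Tet2 (2.47 ± 0.13, adjusted p = 1.07e-05) were higher in the GFP IP. Relative to the median gene they stood at 6.19, 2.73 and 3.15. Over input, Tet1 and Tet2 stood at 0.00 and 0.28 with GFP, neither passing, and at −2.06 and −2.19 with PABP1. Their difference between the IPs thus lay mostly in the PABP1 IP. Within slides 1 and 2 Dazl was at 5.29 and 5.96 (5.57 with slide as a block), Tet1 at 2.11 and 2.18 (2.14) and Tet2 at 2.34 and 2.66 (2.49). With normexp Dazl was at 3.66 (adjusted p = 0.00264), Tet1 at 1.28 (adjusted p = 0.0192) and Tet2 at 1.12 (adjusted p = 0.0107). Pabpc1 was at −1.08 ± 0.68 (adjusted p = 0.187); it was at −0.85 (adjusted p = 0.00504) with slide as a block, at −1.53 (adjusted p = 0.0498) with array weights and at 0.35 with quantile normalization.

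Zfx, an X-linked transcription factor gene, was 23.7-fold higher (4.57 ± 0.14, adjusted p = 9.11e-06), although another probe of it read 0.18. Klhl28 (4.23), the RNA-binding gene Rbm47 (4.13), the deubiquitinase gene Otud4 (4.02, other probes 1.19 and 3.80), the splicing regulator gene Srek1 (3.96, other probes 2.69 and 2.07), the kinase gene Taok1 (3.95) and Dcaf12l1 (3.95) followed. Over input, Srek1 stood at 0.08 with GFP and −3.88 with PABP1, and Taok1 at −0.76 and −4.71. The other higher genes named here stood at 1.52 to 3.26 over input with GFP. Among the lowest were Tyrobp, a signalling adaptor of immune cells, 20.7-fold (−4.37 ± 0.19, adjusted p = 9.11e-06), the neuropeptide gene Npb (−4.01), Tmem126a (−3.99), Ly6g6c (−3.84), the G-protein subunit gene Gng13 (−3.74), Uxt (−3.69), Plac8 (−3.64) and Tm4sf5 (−3.62).

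Of 39 RNA granule genes 28 were higher and 6 lower, with Ago2 at 3.46 ± 0.14 and Elavl2 at 3.27 ± 0.13; limma's camera gave adjusted p = 8.89e-09, and this alone of the list calls held with an estimated correlation (adjusted p = 0.0241 with an estimated correlation). Of 16 DNA methylation genes 9 were higher and 3 lower, such as the maintenance methyltransferase gene Dnmt1, 9.36-fold higher (3.23 ± 0.18), and Ehmt1 (2.82 ± 0.16). The camera test here gave adjusted p = 0.00214 and adjusted p = 0.223 with an estimated correlation. Of 20 Polycomb genes 10 were higher and 3 lower (9 and 3 adjusted over the list alone), with Mtf2 at 3.11 ± 0.13 and Rnf2 at 2.65 ± 0.12, whose second probe read −0.45. For the group camera gave adjusted p = 0.00212 and adjusted p = 0.0926 with an estimated correlation. Of 34 genes for ER-made proteins 18 were higher and 9 lower, such as the growth factor receptor gene Igf1r (2.95 ± 0.16) and Gpc4 (5.64-fold), with camera adjusted p = 0.00212 and adjusted p = 0.0926 with an estimated correlation. Other Ago2 probes read 2.07, 2.26 and 1.93. Over input, Igf1r stood at 0.13 with GFP and at −2.82 with PABP1. For the RNA granule, DNA methylation and ER lists the counts adjusted over the list alone were the same. Relative medians of these 4 lists were 2.40, 1.20, 1.37 and 1.28. Before subtraction of the median gene they were 1.70, 0.45, 0.81 and 0.50 within slide 1, 1.94, 0.68, 0.53 and 0.83 within slide 2, and 1.75, 0.56, 0.74 and 0.64 with slide as a block.

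The DAZL target, germ cell and mitosis lists also passed camera as higher in the GFP IP than in the PABP1 IP, though none did with an estimated correlation. Of the 11 DAZL targets 9 were higher and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.000362, adjusted p = 0.0926 with an estimated correlation). Sdad1 (3.77 ± 0.30, second probe −0.71), Tex19.1 (3.63 ± 0.15), Suz12 (3.09 ± 0.24), Sall4 (2.65 ± 0.25, second probe −0.52), Casp2 (2.20 ± 0.14), Sox2 (1.82 ± 0.13), Casp9 (1.56 ± 0.23) and Nanog (0.70 ± 0.12) were among those higher. Pou5f1 (−2.04 ± 0.25) and Tpx2 (−0.84 ± 0.18) were lower. Sox2, Casp9, Nanog and Tpx2 did not pass with normexp, and Tpx2 did not pass with quantile normalization (−0.47, adjusted p = 0.0560), scaling to the median (−0.38, adjusted p = 0.307), the percentile over detected probes (−0.44, adjusted p = 0.0801) or centring (−0.21, adjusted p = 0.412), nor Nanog on slide 2 alone (adjusted p = 0.0751). Of 18 germ cell genes 9 were higher and 5 lower (9 and 5 adjusted over the list alone), including the receptor gene Kit (3.65 ± 0.23) and the germ cell determinant Prdm1 (3.11 ± 0.23). The germ cell list includes Dazl itself and Tex19.1, which is also in the target list. It was not tested without them, so its call is not separate from theirs. Camera gave here adjusted p = 0.0243, 0.0619 after centring, and adjusted p = 0.399 with an estimated correlation. Of 37 mitosis genes 13 were higher and 8 lower (12 and 8 adjusted over the list alone), including the chromosomal passenger genes Cdca8 (1.38 ± 0.14) and Incenp (1.18 ± 0.13), which did not pass with normexp (adjusted p = 0.209 and 0.338); camera gave adjusted p = 0.0438 and adjusted p = 0.223 with an estimated correlation. That call ended without the first PABP1 IP (adjusted p = 0.0855), without the first GFP IP (0.0547) and with normexp (0.317, median −0.02). Incenp stood at −0.26 over input with GFP and at −1.44 with PABP1. Medians of the target, germ cell and mitosis lists were 1.82, 0.63 and 0.28, and the target median lay 5.64-fold above the median gene. Within slide 1 they were 1.80, 0.43 and 0.14, within slide 2 they were 1.81, 0.54 and 0.13, and with slide as a block 1.79, 0.69 and 0.18.

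Respiratory chain mRNAs were lower almost throughout: 69 of 73 were lower and 0 higher (69 and 0 adjusted over the list alone), with Cox6b1 at −3.48 ± 0.13 and the complex I gene Ndufs6 at −3.38 ± 0.15. Limma's camera gave adjusted p = 5.03e-10 and adjusted p = 0.314 with an estimated correlation. Of 79 ribosomal protein genes 56 were lower and 0 higher (56 and 0 adjusted over the list alone), such as Rpl24 (−2.76 ± 0.14) and Rpl27a (−2.51 ± 0.14, second probe 1.52); camera gave adjusted p = 6.26e-05, 0.124 with quantile normalization (median −0.16, or 0.17 relative to the median gene, the other direction), and adjusted p = 0.626 with an estimated correlation. Of 31 proteasome genes 27 were lower and 2 higher (27 and 2 adjusted over the list alone), with Psma6 at −2.73 ± 0.20 and Psma5 at −2.19 ± 0.16; camera gave adjusted p = 0.00212, 0.0846 with quantile normalization, and adjusted p = 0.423 with an estimated correlation. Against random lists matched on input level, the respiratory median of −2.37 lay below their range of −1.54 to −0.90. The ribosomal median of −1.50 lay inside −1.64 to −1.12 and the proteasome median of −1.45 inside −1.54 to −0.37. Relative medians were −1.69, −0.82 and −0.77. They were −1.61, −0.40 and −0.63 within slide 1, −1.87, −1.12 and −0.84 within slide 2, and −1.69, −0.76 and −0.77 with slide as a block. Feeder markers were lower in the same comparison, 22 of 30 against 3 higher (22 and 3 adjusted over the list alone; median −1.28, adjusted p = 0.0982). They passed with the replicate block (adjusted p = 0.0399), with normexp (0.0310) and on slide 1 alone (0.0352). Relative to the median gene they were at −0.73 within slide 1, −0.34 within slide 2 and −0.60 with slide as a block.

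Lists that did not pass camera between the IPs had counts higher and lower of 5 and 7 for TET enzymes (adjusted p = 0.754), 9 and 6 for naive (0.0589), 8 and 8 for core (0.231) and 4 and 3 for primed pluripotency (0.231), 1 and 6 for primitive endoderm (0.743), 2 and 0 for two-cell-like markers (0.242), 8 and 15 for translation factors (0.754), 3 and 13 for histones (0.396), 5 and 4 for non-coding RNAs (0.254) and 8 and 7 for apoptosis (0.231). Adjusted over the list alone, primitive endoderm had 1 and 5, and histones 2 and 13. Medians of the TET (−0.23), core (−0.60), primed (−0.19) and translation (−0.59) lists were negative under an upward camera direction, and the means of the core (0.33) and primed (0.22) lists were positive; all 4 medians and that of the histones (−0.56) turned positive with quantile normalization. In that setting the naive (adjusted p = 0.00302) and translation (0.00775) lists passed as higher. The primitive endoderm median (−0.86) was 0.08 with normexp, and that of the apoptosis list lay at 0.00, between 0.06 within slide 1 and −0.06 within slide 2.

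**Figure D3:**
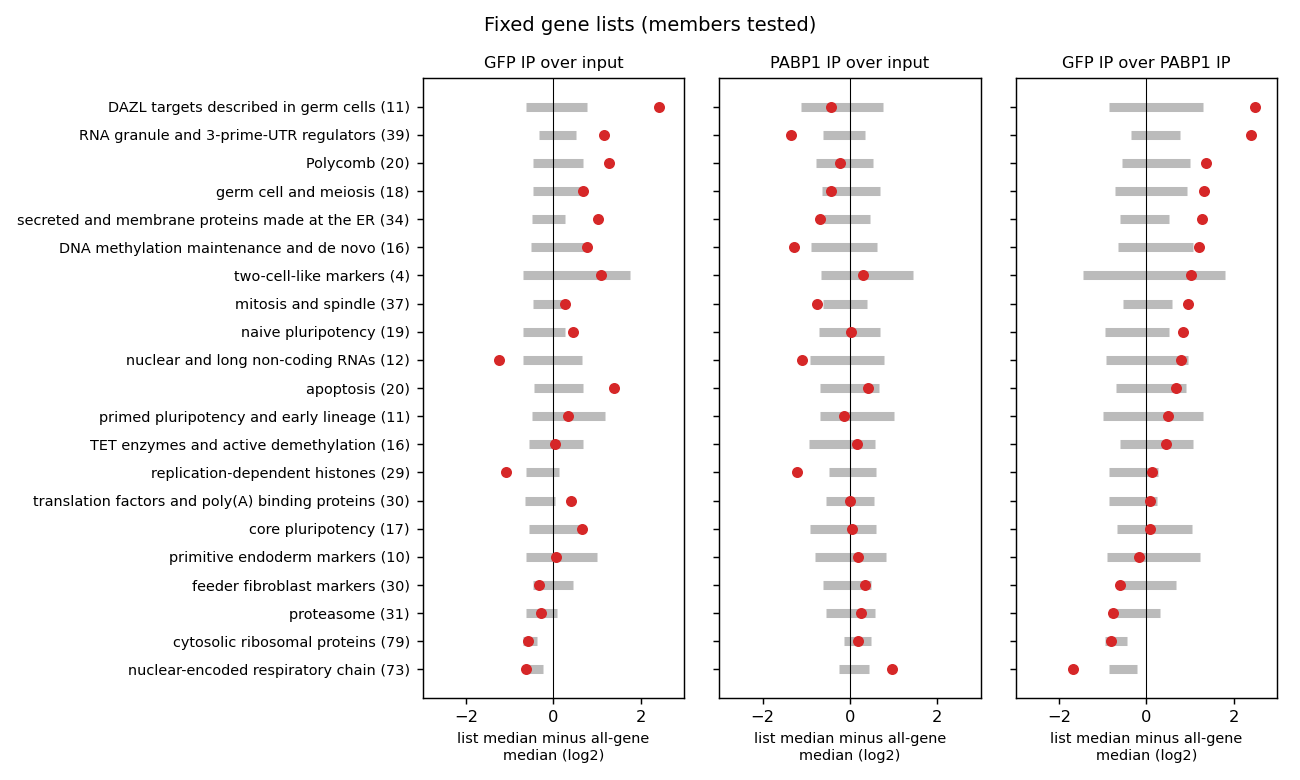
Median log2 ratio of each tested gene list minus the median of all genes (horizontal, red points) in GFP IP over input, PABP1 IP over input and GFP IP over PABP1 IP, with the central range of medians of 10000 random lists matched on input level (grey bars) and the number of tested members after each name. RNA granule regulators (1.16, −1.36 and 2.40) and the respiratory chain (−0.62, 0.97 and −1.69) move in opposite directions, and the sign of several list medians before subtraction, such as the TET, naive and mitosis lists in GFP IP over input, turned with scaling to the median.

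Between the IPs, 3459 genes were higher in the GFP IP and 6983 lower (33.1% higher). With slide as a block the counts were 3905 and 8211, within slide 1 alone 3258 and 7000, and within slide 2 alone 3118 and 6712. The share higher was 46.1% with the 75th percentile over probes detected on all arrays, 46.8% with scaling to the median and 54.0% after centring. With normexp 1093 were higher and 3103 lower.

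Some genes were called in the same direction in both IPs. Against input, 1369 genes were higher in both IPs and 2139 lower in both, where independent lists of these sizes would share 1067 and 1614; with unchanged groups set against the same 3 inputs, 20 simulations shared 0 and 0, but unchanged groups yield hardly any passing genes, so those zeros are no measure of shared recovery. The covariance of the log2 ratios across genes was 0.431 against a simulated 0.0442, while their correlation of 0.282 was below the simulated 0.445. Both comparisons used the same inputs, and 3 inputs do not give each IP 2 of its own, so part of the excess may come from the shared controls. In opposite directions, 721 genes were higher in the GFP IP and lower in the PABP1 IP, and 1832 lower in the GFP IP and higher in the PABP1 IP. Of the 3109 genes higher in the GFP IP than in input, 1988 were also higher than in the PABP1 IP, 669 did not pass against it and 452 were lower than in it.

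**Figure D4:**
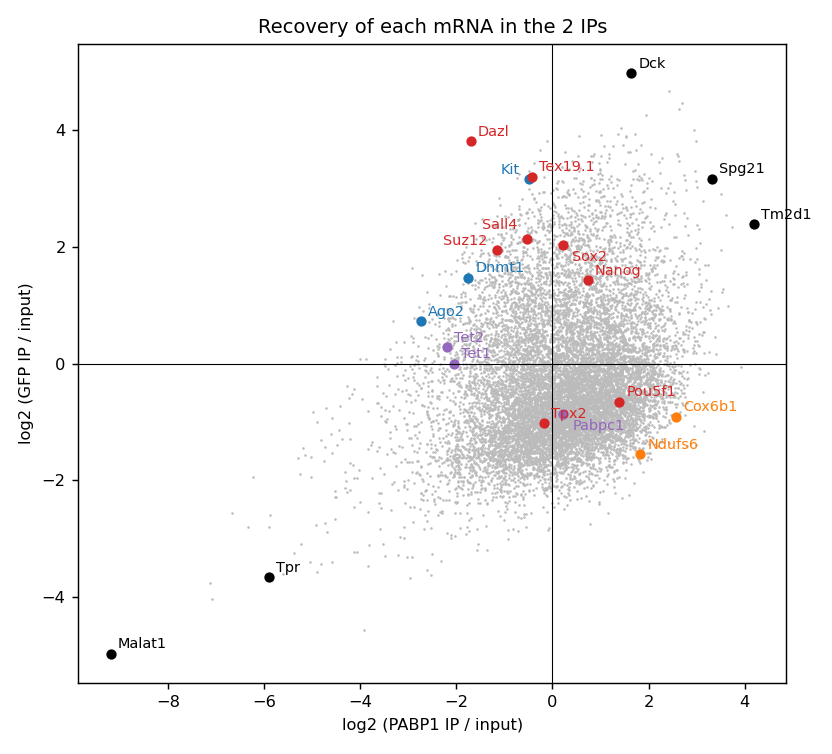
Log2 ratio of each tested gene in PABP1 IP over input (horizontal) and GFP IP over input (vertical), with named genes coloured by group. Red marks Dazl and described targets, blue other regulators, purple TET genes and Pabpc1, and orange the respiratory chain. A gene below background in a group, such as Malat1 in the PABP1 IP, is drawn at its measured value. That value can overstate the ratio, and the bound on it is no larger in size. Dazl lies at 3.81 and −1.70, Tet1 at 0.00 (0.53 with scaling to the median) and −2.06, and Cox6b1 is higher than input with PABP1 (2.56).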

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

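Fits to slide 1 or slide 2 alone and centring on the median ratio were tests chosen only after the result was seen. Where not stated otherwise, the cause was not tested. Among the named genes, the only value counted as a turned sign with a passing test was that of Tet1 in GFP IP over input. It moved from 0.00, which has no clear sign, to 0.53 with scaling to the median, a setting that moves the ratios of a pair of groups together. With normexp, genes higher and lower were 581 and 962 for GFP IP over input, 1643 and 639 for PABP1 IP over input, and 1093 and 3103 between the IPs, genes higher in both IPs than in input fell to 79, and 3 lists were higher in PABP1 IP over input. With a 2-fold minimum, GFP IP over input had 1953 higher and 3893 lower, PABP1 IP over input 2369 lower, and 590 genes were shared, since fewer genes can pass. Genes lower in GFP IP over input were 3118 with scaling to the median and 3794 after centring, which gave 4347 lower between the IPs. For lists, quantile normalization left 2 lower in GFP IP over input, 6 lower in PABP1 IP over input and 1 lower between the IPs. In PABP1 IP over input, lists higher numbered 2 with scaling to the median, the percentile over detected probes, the probe mean, the slide block, slide 2 alone and centring, and 5 without a filter on dim probes; lists lower numbered 4 with scaling to the median, 5 with the probe mean, the slide block and slide 2 alone, and 6 on slide 1 alone. Without the filter 12 lists were higher in GFP IP over input. With an estimated correlation, lists higher and lower were 0 and 0 in GFP IP over input, 0 and 0 in PABP1 IP over input, and 1 and 0 between the IPs; with fry, which does not compare a list with other genes, they were 11 and 9, 3 and 6, and 11 and 7. Leaving out each array in turn, GFP IP over input had 2734 to 3074 higher and 5335 to 6688 lower with 5 to 8 and 4 to 5 lists, PABP1 IP over input 4023 to 5033 higher and 3095 to 3749 lower with 1 to 2 and 2 to 5 lists, the IPs 2969 to 3528 and 5523 to 7205 with 6 to 8 and 3 to 4 lists, and the overlap 1158 to 1372. The highest list counts (8 in GFP IP over input, 2 and 5 in PABP1 IP over input) came without the first input, 2 lists were higher in PABP1 IP over input without the second input, and without the second PABP1 IP 2 were higher and 4 lower in it. A lone PABP1 array was then assumed to vary like the other groups. With the replicate number as a block, counts were 3096 and 6361, 4768 and 3679, and 3331 and 6456, and the overlap 1340. Deviations of same-numbered arrays from their group means correlated at −0.74 to 0.62, following the slide, so the numbers were not read as pairs. Over all settings, 269 counts stayed within 1.5 times the reported value, 27 rose and 22 fell beyond that. Among named genes 2984 values kept direction and call, 68 lost the call, 16 gained it, 47 moved beyond the spread in the authors' deposited table, which has no test, and 1 turned. Of list tests 518 kept their call and 32 lost it. That tally follows only lists that passed with the reported settings, so calls gained by other lists, given above, are not in it. The gene and list tallies also leave out the 2-fold minimum. There, named genes that lost the call numbered 1 in GFP IP over input, 4 in PABP1 IP over input and 2 between the IPs.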

Other observations

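The tests of Dazl, the gene-by-gene test of probe differences, and the separate tests of the respiratory list in each IP were tests chosen only after the result was seen.

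Some further values of germline and pluripotency mRNAs were chosen here after they were seen. Kit was at log2 3.17 ± 0.21 over input and the transposon-silencing paralogue Tex19.2 at 2.51, and Prdm1 was at 2.05. Among core pluripotency genes Lefty2 stood at 1.61 and Lin28a at 1.12, while Gdf3 (−1.37), Nodal (−1.02) and Pou5f1 (−0.66) stood below input. Klf5 was at 1.61 over input but at −1.45 in PABP1 IP over input. The methylation genes Dnmt1 and Hells were likewise at 1.48 and 1.91 with GFP and at −1.75 and −1.25 with PABP1. Among base-excision genes of the demethylation list, Mbd4 (−1.58) and Lig3 (−1.26) were below input in the GFP IP, and Smug1 (1.20) was above.

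Among non-coding RNAs, Neat1, which builds nuclear paraspeckles, was at −2.25 in GFP IP over input and −2.69 in PABP1 IP over input, and the imprinted Meg3 at −2.60 and −2.38. The snoRNA host Snhg5 (−1.11 and 1.14) was below input with GFP and above it with PABP1, while Snhg8 was at −1.94 and −5.02. The mitotic genes Cenpf (−1.53 and −3.28) and Mki67 (−2.01 and −2.35), which have very long transcripts, were below input in both IPs; transcript length was not analysed here. Feeder markers had medians of 1.17 to 1.87 in the GFP IPs, 2.09 to 2.37 in the inputs and 2.05 to 2.75 in the PABP1 IPs, on the scaled log2 scale.

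Respiratory chain mRNAs were lower in the GFP IP and higher in the PABP1 IP than in input. With normexp and quantile normalization, which unlike shifts of whole arrays can move a list against all genes, the median relative to all genes stayed at or below −0.43 with GFP and at or above 0.36 with PABP1, and slide did not account for it either, with medians between the IPs of −2.23 and −2.53 within the slides. The prediction that compression of signal at high abundance caused both parts gave a mixed answer and was split by IP. The PABP1 part, at 1.21, lay above the range of 0.00 to 0.67 for random lists matched on input level. The GFP part, at −1.13, lay inside the range of −1.15 to −0.76, near its lower edge. Across all genes, however, GFP IP over input had a Pearson r of only 0.016 with mean level (Spearman 0.028). Whether depletion from the GFP IP was shared by abundant mRNAs at large thus stays open. Short transcripts remain open as a candidate explanation for the PABP1 part, as lengths were not analysed here.

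Probes of 1 gene often disagreed. Over 3058 genes with 2 probes detected on all arrays, the spread of the probe difference in PABP1 IP over input was 1.89 times that of input 3 over inputs 1 and 2. This lay between the limits set beforehand for noise (1.5) and against it (2). The comparison was uneven, because input 3 was a single array on the other slide from inputs 1 and 2. That widens the spread between inputs and lowers the ratio, so the ratio cannot decide. Limma was therefore run gene by gene. The probe difference passed in 1450 genes (47.4%), which argues against measurement noise as the whole cause. If some probes read transcripts, such as unspliced or alternative forms, that both IPs recover poorly, the probe differences should correlate between the IPs measured against separate inputs. The r across genes was 0.2 (bootstrap range 0.16 to 0.244), between the limits set for and against. The inputs were split by slide, with inputs 1 and 2 on slide 2 for GFP and input 3 on slide 1 for PABP1. A slide effect on probes could therefore lower r, and the bootstrap over genes does not cover it. Such transcripts may contribute, but this stays open.

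Dazl was the mRNA with the largest difference between the IPs. A single faulty probe is argued against by the second probe, well above background on the 3 GFP IPs and on 0 of the inputs, whose log2 difference from input was read as 2.71 and bounded at 2.48 or more. Recovery of mRNA-protein complexes in general predicted Dazl above input with PABP1 too, and its value was −1.7. With normexp it was −0.83 and no longer passed, but was not above input either. As the PABP1 IP was itself selective, this speaks only to complexes recovered with PABP1. It cannot test RNA that sticks to the GFP antibody or beads. DAZL binding its own mRNA is a hypothesis. If GFP is joined to DAZL, pull-down by nascent protein on ribosomes could also place Dazl at the 99.9 percentile of GFP IP over input, and no control IP that would part these was analysed here.

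For GFP IP over input, 1 of the 10 splits of the 6 arrays, the real one, gave 9489 genes past the threshold, and the highest other split gave 0; with 10 splits a share under 0.05 cannot be reached.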
